A study of Mus musculus with 6 samples.

How the data were processed

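Total RNA of whole ileum from 6 mice was measured on Affymetrix mouse gene arrays, with 3 control mice and 3 mice labelled Gata6 KO, as the sample titles state. The authors deposited log2 values per probe set, 1 column per mouse, made with Affymetrix Expression Console per the submitters' processing notes, which give no version. The methods of background correction, normalization and probe set summary are not given in the sources used here, and the log base was inferred from the range of the deposited values. All further steps started from these values, with no scaling of arrays in the main setting.

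The value table holds 35557 probe sets with no missing value. The probe table pairs 21789 of them with 1 gene symbol and 1621 with several, and does not list 12147. Probe sets with several symbols, or not listed, stayed out of the tests of genes and lists; they were tested only in the fit of every probe set on its own, and no single gene was named from them. The gene identifiers of 21698 probe sets with 1 symbol were found in the RefSeq gene table of assembly GRCm38.p6, used for names and chromosomes; no symbol changed. The list of neighbours of Gata6 was written by gene name and not built from positions. For each of the 999 genes with more than 1 probe set, the one with the highest mean over the 6 arrays was taken, which left 19938 genes. Among named genes with more than 1, the dimmer probe set of Ccl25, at a mean of 3.73, had a log2 fold change of -0.16, against -3.84 for the one used. No filter on dim genes was applied.

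Genes were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes, 1 coefficient for Gata6 KO minus control, two-sided, and Benjamini-Hochberg adjustment over all genes; the threshold was an adjusted p of 0.05. The standard error (SE) is the moderated one. Lists of genes for epithelial cell types, regions, metabolism, states and other cell types were fixed before the data were examined, 43 in all. Lists with at least 4 measured genes were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the 42 lists; the red blood cell list, with 3 measured genes and none that passed over all genes (2 lower adjusted over the list alone), was not tested. Named genes followed a rule fixed at the same time: Gata6, Gata4 and Gata5, the 15 genes per direction with the largest change among those that passed and whose groups did not overlap, and up to 4 members with the smallest p per epithelial or state list, or 2 per list of other cells, handling or flanking sequence. Gene models without a name were counted and not described. Members that make up a count of 5 or fewer are named after their values were seen where they fall outside this rule.

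The fit was tested on simulated arrays with the control means and moderated variances of the 19938 genes, 3 arrays per group, and 200 changed genes in each of 5 simulations. It recovered 46.6% of genes changed by 0.5 on the log2 scale, 98.8% of those changed by 1 and 99.7% of those changed by 2, and 4.90% of calls were false. Camera called 100% of simulated lists shifted by 0.5 and 2.00% of unshifted ones; simulated genes were independent, unlike real ones. Alternatives covered scaling of arrays, filters on dim genes, the choice of probe set, moderation, array weights, the replicate number as a block, leaving out each array, covariates for lymphoid tissue and muscle, and other set tests. Figures were drawn with matplotlib 3.10.9.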

Results

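Transcripts of whole ileum, the last part of the small intestine, were measured on Affymetrix mouse gene arrays in 6 mice, with 1 array per mouse. Of these, 3 were controls that carried only a tamoxifen-inducible Cre recombinase under the Villin promoter, which is active in intestinal epithelium. The other 3 also carried floxed alleles of Gata6, a zinc finger transcription factor, and are labelled Gata6 KO. All mice received tamoxifen on 5 days at 6 to 8 weeks of age, and tissue was taken 28 days later. Across all probe sets, arrays of the same group correlated at 0.987 to 0.992 and arrays of different groups at 0.980 to 0.984. The median log2 signal lay between 3.41 and 3.44 on the control arrays and between 3.33 and 3.38 on the KO-labelled arrays. The lower quartile was 1.77 to 1.80 on control and 1.67 to 1.73 on KO-labelled arrays. The upper quartile was 5.35 on control and 5.40 to 5.43 on KO-labelled arrays, so the spread of signal differed between the groups. The number of arrays limits the precision. Control replicate 3 read 2.31 for Xist, the RNA that silences an X chromosome in females, against 7.39 to 7.81 on the other arrays. It also read 5.30 for the Y-linked gene Eif2s3y, which lay between 0.27 and 0.61 on the others. The labels give no sex, but these signals are those of a male for control replicate 3 and of females for the other arrays. Sex was thus not balanced between the groups and was not modelled. The fit without control replicate 3 holds only arrays with female signals. It called 679 genes, and 659 of these were also called with all 6 arrays.

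The first question was whether the targeted gene itself differed. Gata6 did not fall: its log2 signal was 6.31, 6.33 and 6.50 in the controls and 6.93, 6.81 and 6.86 in the arrays labelled Gata6 KO. The log2 fold change was 0.49 (SE 0.08, n = 3 per group), 1.41-fold higher in the KO-labelled arrays, with a limma adjusted p of 0.0162. The signal of Gata6 itself thus does not bear the label out, so directions below are given for the arrays labelled Gata6 KO. Where the probe set lies relative to the floxed exons is not given in the sources used here, and a probe set outside the deleted part checks nothing. Whole ileum also holds muscle and connective tissue, where the Villin promoter is not active. Gata4, which the epithelium of the more proximal intestine uses, read 3.13 and 3.01 in the 2 groups, below the array medians, with a log2 fold change of -0.11 (SE 0.13, limma adjusted p = 0.637). Gata5 had a log2 fold change of -0.38 (SE 0.16), which also did not pass (limma adjusted p = 0.194). Of the 8 GATA factors and cofactors on the list fixed for them, Gata6 alone passed, both over all genes and adjusted over the list alone, and camera did not call that list (adjusted p = 0.544). The limma adjusted p of Gata6 rose to 0.0501 without control replicate 1, 0.0584 without Gata6 KO replicate 1, 0.0573 without replicate 2 and 0.0623 without replicate 3 of that group, with fold changes of 0.46 to 0.55 over all 6 such fits. With the mean of the smooth muscle list as a covariate the log2 fold change was 0.56 with a larger SE of 0.14, and the adjusted p 0.159. The adjusted p was 0.0695 without moderation and 0.130 without control replicates 1 and 3.

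**Figure D1:**
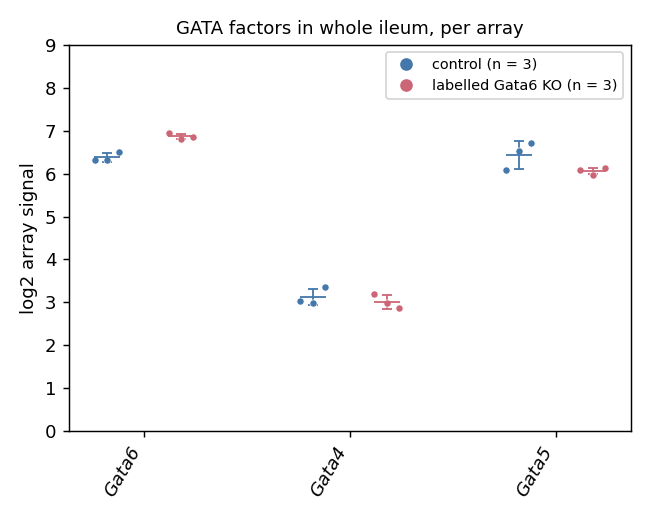
Log2 array signal of Gata6, Gata4 and Gata5 in whole ileum, 1 point per array, with bars at the mean and SD of 3 control and 3 KO-labelled arrays. The KO-labelled points for Gata6 lie between 6.81 and 6.93, above the controls at 6.31 to 6.50.

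The comparison of the 2 groups asked which ileal transcripts differed 28 days after tamoxifen. The stem cell marker Olfm4 fell in the arrays labelled Gata6 KO from a log2 signal of 9.27 ± 0.13 to 3.05 ± 0.53 (SD, n = 3), below the array medians. Cps1, which makes carbamoyl phosphate for citrulline synthesis, fell from 9.60 ± 0.06 to 3.65 ± 0.84 (SD, n = 3), with 1 KO-labelled array, at 2.68, below the array medians. Mttp, which loads lipid onto nascent lipoproteins, fell 18.1-fold (-4.18, SE 0.18) and sucrase-isomaltase, Sis, 12.2-fold (-3.61, SE 0.40). In the other direction Sptssb, a small subunit of serine palmitoyltransferase, rose from 1.98 ± 0.64, below the array medians, to 6.43 ± 0.16 (SD, n = 3), and the cytochrome P450 gene Cyp2c55 rose 18.7-fold (log2 fold change 4.23, SE 0.66). Retnlb, a goblet cell product with antibacterial activity, rose 10.5-fold, from 5.67 ± 0.96 to 9.06 ± 0.06 (SD, n = 3).

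In all, 995 of 19938 genes were higher and 648 lower in the arrays labelled Gata6 KO at a limma adjusted p under 0.05, and 4928 had an unadjusted p under 0.05. At least 2-fold changes made up 163 of the higher and 196 of the lower genes, and at least 4-fold changes 31 and 55. In all 1643 called genes the 2 groups did not overlap, against 29.3% of all genes tested and the 10% that chance gives for 3 against 3. With 3 arrays per group the call itself all but requires this, so it is no separate support. Centring each array on its median moved the split to 1562 higher and 565 lower. The higher count was 630 without control replicate 1, 393 without control replicate 3, and 567, 320 and 397 without Gata6 KO replicates 1, 2 and 3; the lower count was 286 without control replicate 3, and 306, 277 and 329 without those 3. Without control replicates 1 and 3 together, 25 genes were higher and 11 lower, with 1 control array left.

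Among the 15 genes with the largest decrease Tm4sf5, a tetraspanin-like membrane protein, fell by 4.24 on the log2 scale (SE 0.13), and the small intestinal chemokine Ccl25 fell by 3.84 (SE 0.46). The Paneth cell alpha-defensin Defa39 dropped by 3.79 (SE 0.18), while Apoa1, the main protein of high density lipoprotein, dropped by 3.78 (SE 0.41). Mogat2, which re-esterifies absorbed monoglyceride, decreased by 3.50 (SE 0.24), and the serotonin transporter Slc6a4 decreased by 3.14 (SE 0.17). Itln1, a lectin of Paneth and goblet cells, and the apolipoprotein Apoa4 each fell by 2.96 (SE 0.31 and 0.46). Limma adjusted p of these 8 genes ran from 9.08e-05 to 0.0114. In the KO-labelled arrays the means of Olfm4, Defa39 at 2.49 and the lactate transporter Slc5a12 at 1.82 lay below the median signal of the arrays, so the size of these decreases, and of that of Cps1, is uncertain.

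Among the 15 genes with the largest increase were further cytochrome P450 genes, Cyp2c65 with a log2 fold change of 2.78 (SE 0.15) and Cyp2d34, which rose from 3.19 ± 0.67 to 7.10 ± 0.11 (SD, n = 3). The control means of Cyp2d34 and Sptssb were not shown to lie above background, so the size of their change is uncertain. The sulfotransferase Sult1c2 rose by 3.36 (SE 0.18), and the peroxisomal hydroxyacid oxidase Hao2 by 3.03 (SE 0.30). Fa2h, which hydroxylates fatty acids of sphingolipids, rose by 2.66 (SE 0.25). A4gnt, a glycosyltransferase of gland mucus, rose by 2.64 (SE 0.10) and the lectin Reg4 by 2.63 (SE 0.36). Car2, a cytosolic carbonic anhydrase, rose by 3.25 (SE 0.68) with a limma adjusted p of 0.0321, and lost that call without control replicate 2 (0.0828), control replicate 3 (0.119), Gata6 KO replicate 2 (0.123) or Gata6 KO replicate 3 (0.108). Cyp2c55 lost it without Gata6 KO replicates 1, 2 or 3 (0.05004, 0.0594 and 0.0529). Apoa4 and Slc5a12 lost it without Gata6 KO replicate 1 (0.0554 and 0.0534) or 2 (0.0592 and 0.0573). Of the 104 named genes other than Gata6 that passed, 69 kept the call in each of the 6 fits that leave out 1 array, and none turned direction; without moderation 71 of them lost the call, and with the smooth muscle covariate 60.

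**Figure D2:**
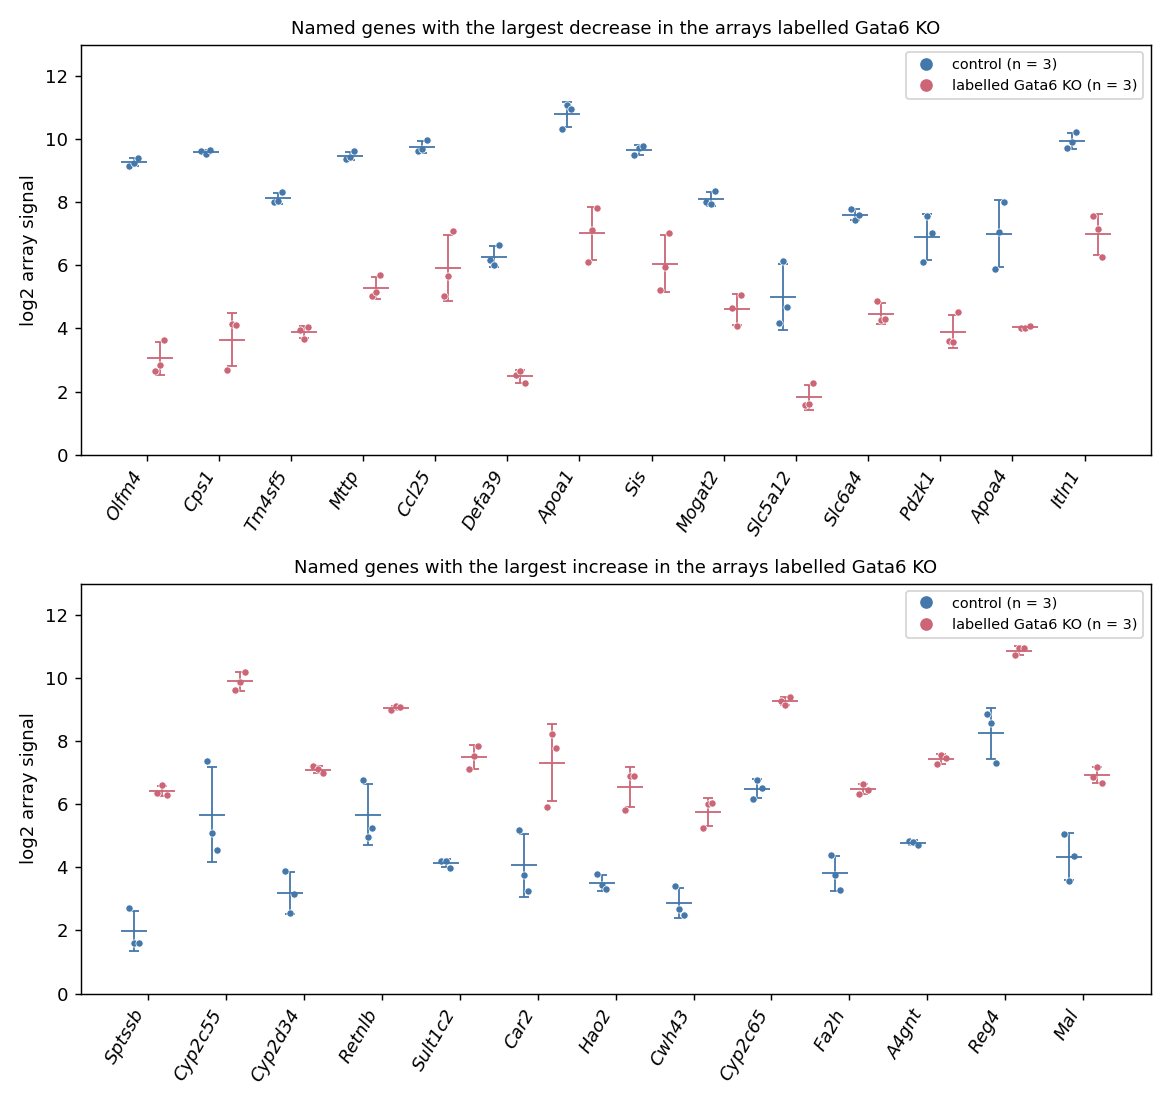
Log2 array signal of the named genes with the largest decrease (top) and increase (bottom), 1 point per array, with bars at the mean and SD of 3 control and 3 KO-labelled arrays. Genes were taken from those whose groups do not overlap, and Olfm4 goes from 9.27 to 3.05.

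Gene lists were tested with limma's camera, which compares a list with all other genes; of 42 lists, 22 were called at an adjusted p under 0.05, 9 higher and 13 lower in the arrays labelled Gata6 KO. With an estimated correlation in place of the preset one, none was called, and the smallest adjusted p was 0.277. By that form 5 lists, 2 higher and 3 lower, had an unadjusted p under 0.05. It rests on the 4 residual degrees of freedom of the 6 arrays, so it has little power here. A call lost with it, here and below, does not show that correlation between genes alone made the call. Fry, which asks only whether the members of a list move on balance one way, called 14 lists, and camera on ranks 19. Camera at the preset correlation also called 6 to 16 lists in splits of the arrays that mix the 2 groups. Each such split mixes them unevenly and keeps part of their difference, so these calls are no measure of false calls. A call by camera at the preset correlation alone was still not taken to show a difference between the groups.

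Genes of the absorptive enterocyte were lower. Of 35 measured genes of brush border digestion and nutrient transport, 21 fell, none rose and 14 did not pass in the arrays labelled Gata6 KO, with a median log2 fold change of -1.08. Adjusted over the list alone, 28 fell and 1 rose. The cationic amino acid transporter subunit Slc7a7 fell by 1.86 (SE 0.10), maltase-glucoamylase, Mgam, by 1.80 (SE 0.10), and the peptide transporter Slc15a1 decreased by 2.08 (SE 0.15). The camera adjusted p was 1.39e-18, and the adjusted p = 0.277 with an estimated correlation. Of 25 genes of lipid absorption and lipoproteins 17 fell, 1 rose and 7 did not pass, or 20 and 2 adjusted over the list alone. Beside Mttp and Mogat2, Npc1l1, the cholesterol uptake protein, fell by 2.12 (SE 0.16) and Dgat1, which makes triglyceride, fell by 1.67 (SE 0.13). The lipid droplet protein Plin2 was the member that rose, by 0.51 (SE 0.12), a call lost without any 1 of the 6 arrays (0.0637 to 0.154). Camera gave this list an adjusted p of 9.86e-13, and the adjusted p = 0.277 with an estimated correlation. In the sterol synthesis list, 8 of 20 genes fell and none rose, 13 adjusted over the list alone, with Cyp51 lower by a log2 fold change of -0.73 (SE 0.11) and Tm7sf2 by -0.66 (SE 0.09). Its camera adjusted p was 4.44e-09, and the adjusted p = 0.408 with an estimated correlation.

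On the distal ileum list 12 of 21 genes fell and 1, Hoxb6, named after its value was seen, rose, or 12 and 2 adjusted over the list alone. The glutamate transporter Slc1a1 fell by 2.04 (SE 0.17) and the peptidase Dpp4 by 1.11 (SE 0.13), and the list's camera adjusted p was 2.78e-05 (adjusted p = 0.277 with an estimated correlation). Of 10 genes of ileal bile acid handling 5 fell and 1 rose, or 6 and 1 adjusted over the list alone. Fabp6, the ileal bile acid binding protein, fell by 2.75 (SE 0.33) and the export pump Abcc2 fell by 2.94 (SE 0.24), while Abcc3, an export pump of the basolateral side, rose by 0.87 (SE 0.08). The mean of Abcc2 in the KO-labelled arrays, 2.86, lay below the array medians, so the size of its decrease is uncertain. Slc10a2, the uptake transporter of bile acids in the ileum, read 9.51 in controls and 9.35 in KO-labelled arrays and did not pass (limma adjusted p = 0.511); it was named after its value was seen. Camera gave 3.35e-04 for this list, and the adjusted p = 0.348 with an estimated correlation. The proximal small intestine list had 11 lower and 2 higher of 35 genes, or 16 and 3 adjusted over the list alone, with the fructose kinase Khk lower by a log2 fold change of -2.04 (SE 0.18). Its camera adjusted p was 4.46e-05, and the adjusted p = 0.392 with an estimated correlation.

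Colon genes were higher: 13 of 40 rose, 1 fell and 26 did not pass in the arrays labelled Gata6 KO, or 15 and 2 adjusted over the list alone, with a median log2 fold change of 0.49. Beside Sult1c2 and Cyp2c55, the folate-processing enzyme Ggh rose by 1.32 (SE 0.08) and the amino acid transporter Slc6a14 by 1.07 (SE 0.08). The member that fell was the protease Prss27, named after its value was seen. The camera adjusted p was 2.77e-06, and the adjusted p = 0.344 with an estimated correlation. Control replicate 1 stood apart for some genes of this list, such as Cyp2c55, but not for Sult1c2, Ggh or Slc6a14. It read 10.96 for the carbonic anhydrase Car1, against 5.68 and 6.87 in the other controls and 12.14 to 12.20 in the KO-labelled arrays, and Car1 did not pass (limma adjusted p = 0.0722). Car1 was named after its values were seen.

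The secretory lineages did not move together. Of 22 Paneth cell genes 12 fell, none rose and 10 did not pass, with a median log2 fold change of -0.93; adjusted over the list alone 14 fell and 2 rose. The matrix metalloproteinase Mmp7, which activates alpha-defensins, fell by 2.65 (SE 0.15), and the secreted phospholipase Pla2g2a also fell by 2.65 (SE 0.23). Camera gave 1.62e-06, and the adjusted p = 0.348 with an estimated correlation. Of 28 goblet cell genes 11 rose and 2 fell, or 13 and 3 adjusted over the list alone. The transcription factor Creb3l1 rose by 1.26 (SE 0.09), the mucin glycosyltransferase Galnt12 by 1.08 (SE 0.07) and the membrane mucin Muc4 by 1.34 (SE 0.17), while St3gal6 and the lectin Zg16 were the members that fell, both named after their values were seen. Camera gave 1.21e-05, and the adjusted p = 0.344 with an estimated correlation. Of 34 enteroendocrine genes 9 fell and 3 rose, or 10 and 3 adjusted over the list alone. The hormone genes Pyy, Tac1 and Sst fell by 1.55 (SE 0.15), 2.25 (SE 0.24) and 0.86 (SE 0.08), and those that rose, Scg3, Pcsk1 and Cpe, serve hormone granules and processing and were named after their values were seen. The camera adjusted p was 0.0180, and the adjusted p = 0.447 with an estimated correlation; the call was lost without control replicate 2 (0.0849), without Gata6 KO replicate 1 (0.0608) and with camera on ranks (0.0649). Of 23 tuft cell genes 6 rose and none fell, or 8 and 2 adjusted over the list alone, among them the kinase Dclk1 by 0.88 (SE 0.13) and the lipoxygenase Alox5 by 0.87 (SE 0.11). Camera gave 0.0414, the adjusted p = 0.598 with an estimated correlation, and the call was lost without control replicate 2 (0.172), without Gata6 KO replicate 3 (0.0766) with fry (0.108) and under 5 other camera settings (0.0543 to 0.140).

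Among dividing and stem cell genes, E2f2 and Birc5 fell by 0.50 (SE 0.10) and 0.38 (SE 0.09), and 48 of 50 proliferation genes did not pass. Adjusted over the list alone none passed, and the median log2 fold change was -0.18. Its camera adjusted p was 1.72e-05, the adjusted p = 0.525 with an estimated correlation, and the call was lost with the smooth muscle covariate (0.564) and with fry (0.155). E2f2 and Birc5 each lost the call without control replicate 1 (0.0821 and 0.105), control replicate 3 (0.0978 and 0.127) or Gata6 KO replicates 1 (0.0868 and 0.0826), 2 (0.0601 and 0.150) or 3 (0.0951 and 0.115). Of 22 stem cell genes Olfm4 and the Wnt feedback gene Axin2 fell, Axin2 by 1.02 (SE 0.15), while Prom1 and the crypt transcription factor Sox9 rose by 1.29 (SE 0.11) and 0.56 (SE 0.09); adjusted over the list alone 3 fell and 6 rose. Axin2 lost the call without control replicate 3 (0.0535) or Gata6 KO replicate 2 (0.0548), and Sox9 without Gata6 KO replicate 1 (0.05004) or 3 (0.0540). That list was not called (camera adjusted p = 0.756), and its median of 0.05 and mean of -0.22 differ in sign. On the Wnt target list, also not called (0.868), Mmp7 and Axin2 fell while Cd44 and Sox9 rose, or 2 and 3 genes adjusted over the list alone.

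Interferon response genes were lower in the arrays labelled Gata6 KO. Of 27 measured, 15 fell, none rose and 12 did not pass, with a median log2 fold change of -0.87, and adjusted over the list alone 24 fell. The viral RNA sensor Ddx58 fell by 0.94 (SE 0.12), the GTPase Mx2 by 2.14 (SE 0.29) and the RNA-sensing synthetase Oas2 fell by 1.86 (SE 0.34). The mean of Mx2 in the KO-labelled arrays, 1.89, lay below the array medians, so the size of its decrease is uncertain. Oas2 lost the call without control replicate 1 (0.0737), control replicate 3 (0.0889) or Gata6 KO replicates 1 (0.0563) or 3 (0.0743). Camera gave an adjusted p of 4.48e-13, and the adjusted p = 0.348 with an estimated correlation. The MHC class II and antigen presentation list had no gene that passed among 15 and was not called (0.779).

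Of 27 genes of fatty acid oxidation 5 rose, or 10 with 1 lower adjusted over the list alone, led by the carnitine carrier Slc25a20 at 0.78 (SE 0.08). Its camera adjusted p was 0.0287, the adjusted p = 0.525 with an estimated correlation, and the call was lost without control replicate 1 (0.112), without Gata6 KO replicates 2 (0.0529) or 3 (0.0763), with fry (0.0539), and under 6 other camera settings (0.0533 to 0.850). Of 24 genes of the unfolded protein response Hyou1 and Asns fell and Ern2 rose, or 4 and 1 adjusted over the list alone, with a camera adjusted p of 3.07e-04 (adjusted p = 0.414 with an estimated correlation), a call lost with fry (0.0641). Of 15 p53 targets Plk2 and Ei24 rose, or 4 adjusted over the list alone, at 0.0399 (adjusted p = 0.348 with an estimated correlation); leaving out control replicate 1 (0.0755) or 3 (0.0509) or Gata6 KO replicate 1 (0.129) or 2 (0.0547), and 5 other camera settings (0.0543 to 0.276), ended that call. Plk2 lost its call in 5 of the fits that leave out 1 array (0.0508 to 0.0859), as did Asns (0.0651 to 0.145) and Ern2 (0.0634 to 0.120), and Ei24 and Hyou1 in all 6 (0.0534 to 0.135). No gene of the gastric epithelium list passed among 19, over all genes or adjusted over the list alone, although camera called it lower at 0.0314 (adjusted p = 0.447 with an estimated correlation), a call lost without control replicate 3 (0.104), without Gata6 KO replicates 1 (0.0547) or 2 (0.0916), with fry (0.133), and under 4 other camera settings (0.0760 to 0.255). Those settings include quantile normalization (camera adjusted p = 0.255) and leaving out genes under percentile 25 (0.142). The mean control signal of the gastric list, 2.59, lay below the array medians. Xenobiotic metabolism genes went both ways, 14 higher and 9 lower of 34, or 15 and 10 adjusted over the list alone, and the list was not called (0.345). Of 29 intestinal transcription factors 4 rose and 4 fell, or 7 and 6 adjusted over the list alone. Pparg, the lipid-sensing nuclear receptor, rose by 1.99 (SE 0.18) and the forkhead factor Foxa1 by 0.87 (SE 0.13; adjusted p = 0.0582 without Gata6 KO replicate 2), while Maf fell by 1.14 (SE 0.12), and this list was not called (0.390). The Notch and Delta list had Dll1 lower among 17 genes (0.879), a call Dll1 lost in 5 fits without 1 array (0.0576 to 0.0966), or 2 lower and 1 higher adjusted over the list alone, and the Hedgehog and BMP list had the BMP antagonist Grem1 higher among 20 (0.566), also 1 adjusted over the list alone.

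Camera also called some lists of markers of other cells and tissues in the piece, and did not call others. The smooth muscle list was higher in the arrays labelled Gata6 KO, with a median log2 fold change of 0.34 over 19 genes. Of these 2 rose, among them the actin-binding protein Tagln by 0.46 (SE 0.10), and Ldb3 fell, or 10 and 1 adjusted over the list alone. Camera gave 9.28e-05, the adjusted p = 0.525 with an estimated correlation, and the call was lost without control replicates 1 and 3 together (0.144) and with fry (0.133). Tagln lost its call in 4 of the fits that leave out 1 array (0.110 to 0.142), and Ldb3 without Gata6 KO replicate 2 (0.0618). The fibroblast list had a median of 0.33 over 22 genes, with Dpt higher (lost in 5 such fits, 0.0704 to 0.155) and none adjusted over the list alone, at 9.99e-05 (adjusted p = 0.525 with an estimated correlation), a list call lost with fry (0.155). Enteric neuron and glia markers rose in 4 of 23 genes, or 5 adjusted over the list alone, at 0.00879 (adjusted p = 0.447 with an estimated correlation), with Stmn2 higher by 0.74 (SE 0.11); the call was lost with genes under percentile 25 left out (0.0636). Macrophage and dendritic cell markers had Cd14 higher among 23, also 1 adjusted over the list alone, at 0.0409 (adjusted p = 0.772 with an estimated correlation). That call was lost without control replicate 3 (0.479), without Gata6 KO replicates 1 (0.460) or 2 (0.0800), with fry (0.469), and under 7 other camera settings (0.0543 to 0.562), and that of Cd14 in 4 fits without 1 array (0.0625 to 0.0939). The pancreatic acinar list was lower, with 5 of 16 genes, or 6 with 1 higher adjusted over the list alone, at 2.79e-04 (adjusted p = 0.414 with an estimated correlation). Of those 5, Clps is also on the Paneth cell list and Zg16 on the goblet cell list, and the trypsin inhibitor Spink1 fell by 2.26 (SE 0.24); without control replicates 1 and 3 the list was not called (0.0844), nor with fry (0.0603). None of the B cell and Peyer patch (21 genes, 0.877), plasma cell (13, 0.397), T and natural killer cell (26, 0.265) and endothelium (20, 0.614) lists was called or had a gene that passed, over all genes or adjusted over the list alone. The mast cell (12, 0.779), neutrophil (12, 0.779) and adipocyte (14, 0.0631) lists were not called. In these Kit, Ly6g, Retnlg and Pparg rose and Ltf and Lipe fell, the same numbers as adjusted over the list alone. Retnlg was named after its value was seen. Mean signals of Ly6g (1.82 in controls, 2.30 in KO-labelled arrays) and Ltf (2.80 and 2.20) lay below the array medians, so their changes are uncertain. Single arrays decided the calls of Ly6g (0.0530 to 0.0701 in 4 fits), Ltf (0.0609 to 0.104 in 5), Lipe (0.121 to 0.143 in 5) and Kit (0.0586 without Gata6 KO replicate 2). The plasma cell and adipocyte lists were called without control replicate 1 (0.0489 and 0.00190), and the T and natural killer cell list without Gata6 KO replicate 3 (0.0307). With the smooth muscle covariate the neutrophil and adipocyte lists were called (0.00392 and 0.0123), and without control replicates 1 and 3 the adipocyte list (1.36e-05).

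Camera did not call the lists that track handling and flanking sequence. Ribosomal protein genes had no gene that passed among 24, over all genes or adjusted over the list alone (0.253), and were called with genes under percentile 50 left out (0.0465) and with the smooth muscle covariate (0.0482). Of 16 circadian clock genes Usp2 fell by 0.77 (SE 0.08), with 1 lower and 1 higher adjusted over the list alone (0.474), and of 22 immediate early and heat shock genes Gadd45g fell by 0.92 (SE 0.11), also 1 adjusted over the list alone (0.818). None of the 4 sex-linked genes measured passed, over all genes or adjusted over the list alone (0.541). Control replicate 3 alone carried the Y-linked signal, and Xist and Eif2s3y had log2 fold changes of 1.80 (SE 1.32) and -1.80 (SE 1.17). With such opposite signs and SE this list could not show a sex difference, and its result does not speak against one. Of 51 genes listed as neighbours of Gata6, 49 lie on chromosome 18 in the gene table, while Tyms-ps lies on another and Ctage5 has none. On this list Greb1l and Mpp7 were higher and B4galt6, Abhd3 and Rnf125 lower, or 4 and 3 adjusted over the list alone (0.140); Greb1l rose by 0.74 (SE 0.09), and Mpp7, Abhd3 and Rnf125 were named after their values were seen. Fry called this list higher (adjusted p = 0.0342). B4galt6 lost its call without Gata6 KO replicate 1 (0.0554) or 2 (0.0650). The median, mean and test differed in sign for 4 lists, those of stem cells, Wnt targets, B cells and Peyer patches, and immediate early and heat shock genes.

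**Figure D3:**
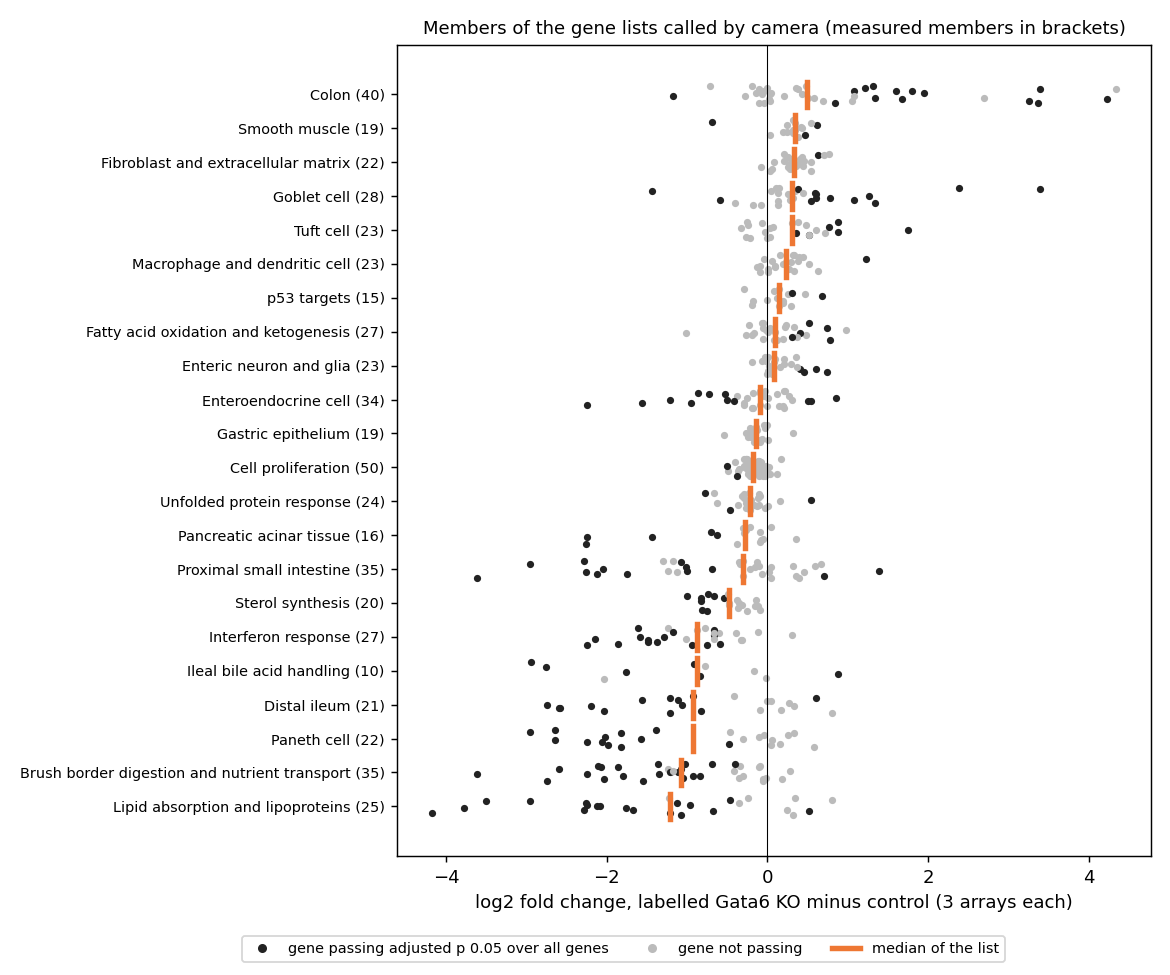
Log2 fold change, arrays labelled Gata6 KO minus control, of the measured members of the 22 gene lists called by camera, 1 point per gene, dark where the gene passed an adjusted p of 0.05 over all genes, with an orange bar at the list median. Medians run from 0.49 for the colon list to -1.22 for lipid absorption and lipoproteins.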

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

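The tests of explanations and of other splits of the arrays in this part were chosen only after the results they bear on had been seen; the fit of every probe set and the covariate fit were not. Of the probe sets left out of the gene tests, 7 with several gene symbols and 44 not listed were higher in the arrays labelled Gata6 KO when every probe set was fitted with limma, and more, 18 and 84, were lower. These made up 1.54% and 1.05% of their kinds, against 3.41% of probe sets with 1 symbol. All 6 probe sets that list several alpha-defensin genes were lower, with log2 fold changes from -1.81 to -1.40.

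Gata6 read higher in the arrays labelled Gata6 KO. An exchange of the labels of the 2 groups would make those arrays the intact ileum, yet 61 of the 64 called members of 5 lists of intact ileum (Paneth, bile acid, distal ileum, lipid and brush border), 95.3%, were lower there. That share argues against an exchange only if intact ileum holds more of these transcripts, which the data cannot show, so it stays open. More muscle and fibroblasts in the pieces could raise Gata6, but 7 of 41 of their markers, 17.1%, had a log2 fold change at or above that of Gata6, and with the smooth muscle covariate its log2 fold change went from 0.49 (SE 0.08) to 0.56 (SE 0.14) and lost its call as the SE grew (limma adjusted p = 0.159), so this source stays open. A transcript that lacks the deleted exons and is still measured, and a response of the gene to its own loss, were not tested.

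Camera called the distal ileum and bile acid lists lower and the colon list higher, though 26 of 40 colon genes did not pass. With an estimated correlation these calls were lost (camera adjusted p = 0.277, 0.348 and 0.344). Colon in place of ileum lowers every transcript that only the ileum makes by the same factor, yet Slc10a2 had a log2 fold change of -0.16 (95% interval -0.49 to 0.16) against -2.75 (-3.53 to -1.98) for Fabp6, which argues against it for the genes that fell. For the genes that rose, 6 posterior Hox genes had a median log2 fold change of -0.023 and none passed, but at a median control signal of 2.50, under the 4.04 of all genes, they exclude nothing, so a small share of colon and loss of Gata6 cannot be told apart. The loss of Gata6 that the design names stays open and untested.

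Camera called the lists of absorptive genes lower and those of muscle and fibroblast markers higher, calls all lost with an estimated correlation. The muscle and fibroblast calls were also lost with fry (adjusted p = 0.133 and 0.155). Of their genes, 2 of 19 and 1 of 22 passed as higher. A lower share of epithelium lowers all epithelial genes alike, but the goblet cell median lay 1.38 above the brush border median on the log2 scale, more than the goblet interquartile range of 0.48, which argues against it as the whole source. A change within the absorptive cells, and a smaller change of tissue share on top of it, stay open.

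Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many genes, the real one with 1643, against 0 at most in the others. Each other split mixes the 2 groups, so their difference adds to the spread within it and lowers the number of genes called. The 0 is therefore no measure of what a random grouping would call. Likewise 1 gave as many lists, the real one with 22, against 16 at most in the others. Camera at the preset correlation called 6 to 16 lists in each of the others, where no gene was called. The others mix the 2 groups unevenly, so part of the group difference stays in them. These list calls are therefore no measure of false calls either. Fry called 14 lists in the real split and 0 in the others, with the same limit from mixed groups. With 10 splits no share under 0.05 can be had.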

How the results depend on the processing

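The alternatives were fixed before the data were examined, except leaving out control replicates 1 and 3 together. The 10 lists for Paneth, goblet, bile acid, proximal, distal ileum, colon, lipid, brush border, sterol and interferon genes kept direction and call under every alternative that tested lists but the estimated correlation; lists were not tested with every probe set on its own. No named gene that passed changed direction in the fits that tested it; the filters on dim genes left 137 and 124 of 145, and the fit of every probe set was not used to follow them, apart from Gata6 (0.49, limma adjusted p = 0.0458) and genes with several probe sets. Of the 104 other than Gata6 that passed, 71 lost the call without moderation, 60 with the smooth muscle covariate, 92 without control replicates 1 and 3, 10 with the B cell covariate and 8 with the replicate block. The higher and lower counts were 1562 and 565 with arrays centred on their medians, 491 and 406 with every probe set on its own, 168 and 106 without moderation, and 75 and 104 with the smooth muscle covariate. At an adjusted p under 0.01 they were 277 and 229, under 0.1 1626 and 1050, and at 1.5-fold or more 480 and 385. Leaving out 1 array gave 320 to 806 higher and 277 to 597 lower, and leaving out control replicates 1 and 3, 25 and 11, with fewer samples in both. The smooth muscle list itself had a median log2 fold change of 0.34 between the groups, so its mean overlaps with the group term. With that covariate the SE of Gata6 grew from 0.08 to 0.14. Calls lost with it therefore do not show that muscle content was their source. For the other settings the cause was not tested. The Gata6 log2 fold change was 0.46 to 0.55 with 1 array left out. It lost its call at 0.49 without moderation (limma adjusted p = 0.0695), at 0.56 with the smooth muscle covariate (0.159) and at 0.54 without control replicates 1 and 3 (0.130), over a range of 0.00597 to 0.159. Lists called were 17 to 22 under other scaling, filters, fits and arrays, 19 with camera on ranks, 0 with an estimated correlation and 14 with fry. The smooth muscle list turned direction with its own mean as covariate (adjusted p = 0.987), by construction. Same-numbered arrays of the 2 groups had correlated deviations over genes of 0.04, -0.04 and 0.15, and not every array correlated best with its own number, so the numbers were not taken to pair the mice; with the replicate block, 766 genes were higher, 475 lower and 22 lists called, and Gata6 stayed at 0.49. Signal near or below the array median limits the folds of genes that fell to it or rose from it.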

Other observations

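The genes in this part were chosen after their values were seen, so they stand as single genes: no list of them was tested, and no explanation. In the arrays labelled Gata6 KO the ornithine carrier Slc25a15 fell by 2.01 on the log2 scale (SE 0.11), ornithine transcarbamylase, Otc, by 1.40 (SE 0.14), the aminotransferase Oat by 1.14 (SE 0.10) and Nags, which makes the activator of Cps1, decreased by 0.67 (SE 0.10). Limma adjusted p of these 4 ran from 2.82e-04 to 0.00808. Of other genes of the urea cycle and arginine breakdown, Asl, Arg1 and Arg2 had log2 fold changes of 0.05 (SE 0.09), 1.32 (SE 0.54) and 0.11 (SE 0.22) and did not pass (limma adjusted p = 0.768, 0.187 and 0.795).

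Among single enzymes that act on sulfur compounds, Ethe1, the persulfide dioxygenase of mitochondria, rose by 2.21 (SE 0.11), the thiosulfate sulfurtransferase Tst by 2.14 (SE 0.16), Mpst by 1.71 (SE 0.14) and Selenbp1, a methanethiol oxidase, by 2.39 (SE 0.24), while the sulfite oxidase Suox fell by 1.25 (SE 0.16). Limma adjusted p of these 5 ran from 2.57e-04 to 0.00527. Among single glycosyltransferases, B3gnt6 rose by 2.01 (SE 0.16) and Gcnt3 by 1.08 (SE 0.22), while the sialyltransferase St3gal4 fell by 1.88 (SE 0.09), with limma adjusted p from 1.83e-04 to 0.0283. B3gnt3, B3gnt7 and Galnt3, looked up with them, had log2 fold changes of 0.10 (SE 0.08), -0.62 (SE 0.16) and 0.26 (SE 0.10) and did not pass (limma adjusted p = 0.483, 0.0643 and 0.169).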
